A study of Homo sapiens with 4 samples.

How the data were processed

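The mRNA of A549 cells was profiled in 4 libraries, 1 each for 3D normoxia, 3D hypoxia, 2D normoxia and 2D hypoxia. Per the labels' protocols, cells were kept for 5 days with 5% serum, on solidified Matrigel or on a culture dish, with 1% oxygen for hypoxia, RNA was isolated with a miRNeasy Micro kit and libraries were made with a TruSeq Stranded mRNA kit. Per the submitters' processing notes, the tools were TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18 and Cuffdiff 2.2.1 with the hg19 build. The gene annotation, the library scaling, the strand setting, read length and sequencing depth are not given in the sources used here.

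The authors deposited 1 FPKM value per gene symbol and library, fragments per kilobase of transcript scaled to library depth, for 26255 symbols. No counts were used, since the values are not counts and no count model fits them. The FPKM sums of the libraries ran from 473503 to 596102, and the 10 highest genes held 10.0%, 10.5%, 7.33% and 8.77% of the sum in the order above, led by FTL (15438, 11584.5 and 5900.06 FPKM) and, in 2D hypoxia, TMSB10 (6579.97 FPKM). Listed at 0 were 9276, 9244, 8207 and 7929 genes. A value of 0 can be a failed estimate, so no fold is given against it.

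Depth was inferred from the commonest low value of FPKM times transcript length, taken as 1 fragment. It was sought among genes with a single annotated transcript (2134 genes, transcripts over 1000 bases). Near that value lay only 70, 84, 89 and 74 genes in the order above. In the order above, 1 fragment on 1 kb was worth 0.0845, 0.0882, 0.0416 and 0.0258 FPKM, and depth came to about 11800000, 11300000, 24100000 and 38700000 fragments. Transcript lengths were taken from GENCODE 29, an annotation of another build than the authors', and served only for lengths. These depths are estimates, and counting errors from them leave out biological and technical variation.

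Values were taken as log2(FPKM + 1), so that log2 ratios understate the differences of low genes, and the 12663 genes with a mean of at least 1 FPKM were kept. With 1 library per group, the 4 pairwise comparisons and the difference of the hypoxia responses were described by size (at least 2-fold either way) with no test. The average effects of oxygen and of culture were tested with limma 3.58.1 in R 4.3.3 (trend, culture and oxygen as additive terms, 1 residual degree of freedom, prior degrees of freedom 4.67), with Benjamini-Hochberg adjustment at 0.05. Nothing in the labels says whether the libraries came from separate experiments, so the p-values measure only the spread between these libraries. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

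The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took genes with at least 5 FPKM in a library of the comparison, without small RNA genes (symbols starting MIR, SNOR, SCARNA, RNU, RNA5, RN7, RMRP or RPPH) and uncharacterised loci (LOC, LINC). It named the 12 highest and 12 lowest genes for hypoxia in 3D, 8 and 8 for each other pair, 6 and 6 for the difference of responses, the 6 called genes of smallest p per direction of each average effect, up to 4 members of each list with the largest log2 ratios, and HIF1A, EPAS1 and ARNT.

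The 25 lists held 500 entries, all found among the symbols: HIF target genes, glycolysis and glucose transport, oxygen-sensing components, oxidative phosphorylation, G1/S and G2/M genes, epithelial junction and keratin genes, mesenchymal genes, collagens, laminins and basement membrane, matrix remodelling enzymes, integrins and adhesion receptors, alveolar type II and lung lineage, mucins and goblet cell genes, unfolded protein and integrated stress response, cholesterol synthesis and uptake, NRF2 targets, interferon-stimulated genes, inflammatory and NF-kB targets, secreted growth factors, stem cell-associated genes, ribosomal proteins, replication-dependent histones, blood cell markers, and endothelial and fibroblast markers. One list and some genes that meet these rules are left out of the text and of the figures' labels. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean log2 expression in 20 bins, and the random range is their central 95% (percentiles 2.5 to 97.5). This describes these libraries and is not a test across replicates.

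The limma fit was tested on simulated data, and the list procedure on lists drawn at random from the real ratios. For the average hypoxia effect (12663 genes, 200 changed, 10 simulations), limma recovered 74.8% of 2-fold and 99.6% of 4-fold changes shared by both cultures, 0.05% of 4-fold changes present in 3D alone, and made 9.5 false calls on average. A gene that responds in only 1 culture is therefore seldom called. The simulated noise was independent between genes and used the fitted variances. False calls from a difference shared by many genes of a library are thus not covered. For hypoxia in 3D, 1 of 20 unchanged lists of 25 randomly drawn genes fell outside the random range. With the same lists shifted by 0.5, 20 of 20 lay above it. The first result follows from the random draw, so it does not cover lists whose members move together. Counting noise was simulated 20 times per comparison from the estimated fragments of 11985 genes.

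The alternatives were a pseudocount of 0.1 FPKM, no filter, a mean of at least 5 FPKM, each library rescaled to a sum of 1000000, rescaling by the median ratio to the geometric mean, and limma without trend or robust. One more, without small RNA genes and genes listed at 0 in any library, was added after seeing the data. No genomic positions are given, since genes are identified by symbol and the reference used for lengths is of another build.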

Results

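RNA was measured in A549 cells, an established human lung adenocarcinoma line, after 5 days either on a plastic dish (2D) or on a bed of Matrigel, a gelled basement membrane extract (3D). Each culture was kept in normoxia or in hypoxia with 1% oxygen, which gave 4 groups with 1 library each. The study asked what characterises the micropapillary-like structures that these cells form in 3D under hypoxia. Expression of 26255 gene symbols was given as FPKM (fragments per kilobase of transcript, scaled to the depth of the library), and 12663 genes with a mean of at least 1 FPKM were compared. Depth was inferred from the commonest low value of each library. It was about 11800000 fragments in 3D normoxia, 11300000 in 3D hypoxia, 24100000 in 2D normoxia and 38700000 in 2D hypoxia. A gene with a 2 kb transcript at 1 FPKM therefore rested on 23.7, 22.7, 48.1 and 77.5 fragments in that order. With 1 library per group, no difference between a pair of libraries has a replicate check, and the counting errors given below cover the sampling of fragments only. The verbs rose and fell are kept for genes that passed limma in an average effect over the 4 libraries.

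The first question was which genes differed between hypoxia and normoxia in 3D, the condition in which the structures form. CA9, a cell-surface carbonic anhydrase, stood highest of the genes eligible to be named, at 4.05 FPKM in normoxia and 199.7 in hypoxia, a log2 ratio of 5.31 with a counting error of 0.21. SLC2A3, a glucose transporter, went from 6.46 to 186.9 FPKM (log2 ratio 4.65), and WISP2, a secreted matricellular protein, had a log2 ratio of 4.51. IGFBP1, an insulin-like growth factor binding protein, was at 29.6 FPKM in normoxia and 604.3 in hypoxia. LOXL2, which crosslinks collagen, had a log2 ratio of 4.08, and NDRG1, ANGPTL4 and STC2 had ratios of 4.01, 3.92 and 3.81. EGLN3, a prolyl hydroxylase that marks HIF proteins for degradation, had a ratio of 3.58, ALDOC, a glycolytic aldolase, 3.34, NDUFA4L2, a mitochondrial protein, 3.32, and the cytokine IL32 3.27.

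Among the genes lower in 3D hypoxia, ADH1C, an alcohol dehydrogenase, was at 14.3 FPKM in normoxia and 0.671 in hypoxia (log2 ratio -3.19), and FCGBP, a protein of mucus, at 27.3 and 2.21 (-3.14). The long noncoding RNA GAPLINC had a log2 ratio of -2.13, PDK4, a kinase that holds back pyruvate dehydrogenase, -2.01, ACOX2, a peroxisomal oxidase, -1.96, DDC, which decarboxylates aromatic amino acids, -1.93, and the tight junction gene CLDN2 -1.87. HIF1A itself, an oxygen-regulated HIF subunit, was at 144.2 FPKM in normoxia and 41.1 in hypoxia (-1.79). HIF1A-AS2 had a ratio of -1.74, but it is antisense to HIF1A and the use of strand in the counting is not given in the sources used here, so its value is uncertain. H3F3A (-3.15) and MTRNR2L2 (-1.72) have near-identical copies elsewhere in the genome and are uncertain for that reason. RNVU1-20, a U1 variant, was at 10.5 FPKM in 3D normoxia and was listed at 0 in the other 3 libraries.

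All 29 measured HIF target genes stood above 0 in 3D, with a median log2 ratio of 1.70, and 27 were at least 2-fold higher. That median was above all 10000 random lists of the same size and expression level, whose central 95% ran from -0.16 to 0.13. Genes of glycolysis and glucose transport had a median of 1.67, with 18 of 23 at least 2-fold higher, among them the lactate exporter SLC16A3 (2.95) and the hexokinase HK2 (2.67). All 28 genes of oxidative phosphorylation stood below 0, with a median of -0.35, below all random lists. UQCRC2 and CYC1, subunits of complex III, were at -0.66 and -0.60. The oxygen-sensing components had a median of 0.05, which changed sign to -0.07 when each library was rescaled to a sum of 1000000. Of them, CITED2, which competes with HIF for a coactivator, was at 1.70. EPAS1, which like HIF1A is an oxygen-regulated HIF subunit, was at 0.03, and ARNT, the partner subunit, at 0.10.

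Matrix and adhesion genes were higher in 3D hypoxia. Collagens, laminins and basement membrane genes had a median log2 ratio of 0.72, with the collagen COL7A1 at 1.89. Matrix remodelling enzymes had a median of 0.48, with the collagen hydroxylase PLOD2 at 2.67 and the lysosomal protease CTSL at -1.65. Integrins and adhesion receptors stood at 0.40 (L1CAM 1.68, SDC4 1.56). Epithelial junction and keratin genes and mesenchymal genes were both above the random range, with medians of 0.39 and 0.37. The desmosomal gene DSP was at 1.57 and the tight junction gene CLDN1 at 1.22, beside the intermediate filament gene VIM at 1.75 and TGFBI, a secreted matrix protein, at 1.79.

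Proliferation genes were lower in 3D hypoxia, since all 20 G1/S genes and all 20 G2/M genes stood below 0 (medians -0.50 and -0.43). CDC6, which licenses replication origins, was at -0.97, PCNA, the replication clamp, at -0.95 and the mitotic activator CDC20 at -0.60. Mucins and goblet cell genes had a median of -0.92, but their members parted, with MUC5AC at -1.42 and MUC1, a membrane mucin, at 2.30. Secreted growth factors stood at 0.37 (EFNA1 1.40), inflammatory and NF-kB target genes at 0.34 (CCL2 2.43, CXCL8 2.02), and cholesterol synthesis and uptake genes at 0.26. NRF2 target genes stood at -0.32 (ALDH3A1 -0.93) and genes of the unfolded protein and integrated stress response at -0.30 (SDF2L1 -1.35, TRIB3 1.13). Ribosomal proteins (0.19), stem cell-associated genes (0.11), interferon-stimulated genes (0.01, mean -0.07, and -0.11 after rescaling to a sum of 1000000) and the 6 measured alveolar type II and lung lineage genes (-0.16, mean 0.07) lay within the random ranges. Replication-dependent histone genes had a median of 0.43, above the random range, with HIST1H4H at 2.70. Most transcripts of these genes lack a poly(A) tail, which mRNA library kits usually select for. The values of this list are therefore uncertain, here and in the other comparisons.

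Of the 12663 genes, 368 were at least 2-fold higher in 3D hypoxia and 141 at least 2-fold lower, and 70 and 23 differed by at least 4-fold. Counting noise alone gave a mean of 5.7 such genes in 20 simulations over the 11985 genes with a known length, against 485 observed. No test was possible for this pair of libraries. After each library was rescaled to a sum of 1000000, the median ratio of all genes moved from -0.02 to -0.14, and 327 genes were higher and 236 lower, so that the share of higher genes went from 72.3% to 58.1%.

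**Figure D1:**
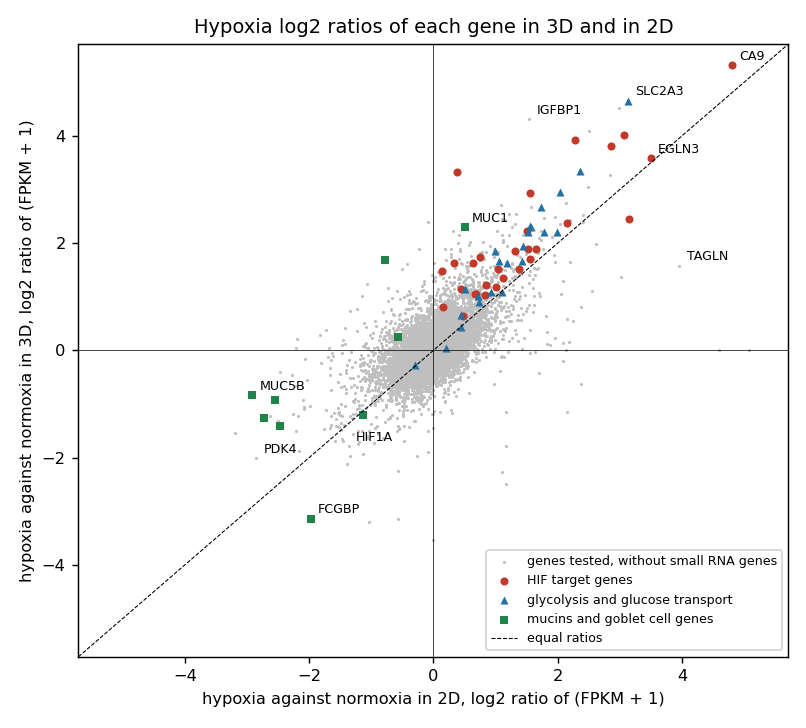
Each point is a gene with a mean of at least 1 FPKM, small RNA genes left out, at its log2 ratio of hypoxia against normoxia (FPKM + 1) in 2D on the x axis and in 3D on the y axis, with 3 gene lists in colour and a dashed line at equal ratios. CA9 lies at 4.80 in 2D and 5.31 in 3D, IGFBP1 lies far above the dashed line (1.54 and 4.31) and TAGLN far below it (3.96 and 1.58).

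The same contrast in 2D showed how the cells responded to hypoxia on plastic. CA9 again stood among the highest named genes (4.0 FPKM in normoxia, 138.5 in hypoxia, log2 ratio 4.80), with TAGLN, an actin-binding protein of contractile cells, at 3.96 and EGLN3 at 3.50. SLC2A3 and NDRG1 had ratios of 3.14 and 3.06. SNAR-E and P2RX6P, at 33.0 and 23.3 FPKM in 2D hypoxia, were listed at 0 in the other 3 libraries, and SNAR-E has near-identical copies. Among the lowest named genes, the calcium-binding S100P was at 22.4 FPKM in normoxia and 1.58 in hypoxia (log2 ratio -3.19), MUC5B, a gel-forming mucin, had a ratio of -2.91, and PDK4 -2.85. SPDEF, a transcription factor of goblet cells, was at -2.72, SLC51B, part of a bile acid exporter, at -2.62, AGR2, a disulfide isomerase needed for mucin folding, at -2.55, the water channel AQP3 at -2.51 and MUC5AC at -2.47.

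In 2D all 29 HIF target genes were again above 0, with a median log2 ratio of 1.12 and 17 at least 2-fold higher, and glycolysis genes had a median of 1.18 (ALDOC 2.35, SLC2A1 1.99). Mesenchymal genes had a median of 0.74, with TGFBI at 1.49 and the cadherin CDH2 at 1.47. Collagens, laminins and basement membrane genes stood at 0.53 (COL5A1 2.56, COL4A1 2.24) and secreted growth factors at 0.41 (PDGFB 3.02). Ribosomal proteins stood at 0.32 (RPLP0 0.79). Mucins and goblet cell genes had the lowest median of the lists, -1.98, with 6 of 9 at least 2-fold lower. The stress response list stood at -0.34 (XBP1 -1.43), NRF2 target genes at -0.30 (ALDH3A1 -2.10), cholesterol genes at -0.29, G1/S genes at -0.27 (MCM7 -0.53), and oxidative phosphorylation at -0.18 (NDUFV2 -0.49). These lists lay outside their random ranges.

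Several lists in 2D lay inside their random ranges. G2/M genes stood at -0.19 (AURKA -0.45), stem cell-associated genes at 0.13 (POU5F1 1.68, uncertain because of its many pseudogene copies), integrins and adhesion receptors at 0.12 (ITGAV 1.05) and inflammatory genes at -0.07 (PTGS2 -2.21, LCN2 -1.66, and CCL2 the other way, at 46.9 FPKM in normoxia and 219.2 in hypoxia). Oxygen-sensing components stood at -0.06 (HIF1A -1.36), alveolar and lung lineage genes at -0.06 (mean 0.07), and matrix remodelling enzymes at -0.03 (mean 0.18). Interferon-stimulated genes (0.08, mean -0.01), histone genes (0.02) and epithelial junction and keratin genes (0.01, mean -0.11) changed sign to -0.05, -0.11 and -0.10 on rescaling to a sum of 1000000. In the last list the keratin KRT18 was at -0.93 and the junction scaffold TJP3 at -1.62.

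In 2D 255 genes were at least 2-fold higher and 201 at least 2-fold lower. Of genes with a known length 438 were, against a mean of 0.45 from counting noise. No test was possible here either. On rescaling to a sum of 1000000, 236 genes were higher and 341 lower, the share of higher genes moved from 55.9% to 40.9%, and the median of all genes moved by -0.13.

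Hypoxia was then taken as an average over both cultures, the only hypoxia comparison with an error term. CA9 rose by a log2 value of 5.06 ± 0.16 (SE), limma adjusted p = 0.000621, and EGLN3 by 3.54 ± 0.11 with the same adjusted p. IL32 rose by 3.06 ± 0.14, the transcription cofactor LBH by 2.46 ± 0.12, the mitophagy receptor BNIP3L by 2.26 ± 0.12 and the chemokine CCL2 by 2.32 ± 0.13. CLDN2 fell by 2.02 ± 0.13 on the log2 scale (adjusted p = 0.00605), and so did UNC13A, a synaptic vesicle priming gene (-1.64), and the antigen-processing genes IFI30 (-1.49) and HLA-DMB (-1.48). OAS1, an antiviral enzyme, fell by 1.41 and the scaffold IQGAP2 by 1.61. HIF1A fell by 1.58 ± 0.15 (adjusted p = 0.00976), while EPAS1 and ARNT did not pass (-0.18 and 0.07, limma adjusted p = 0.473 and 0.722). IGFBP1 did not pass either (2.92 ± 0.59, adjusted p = 0.057), nor did NDUFA4L2 (adjusted p = 0.15).

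Of the 29 HIF target genes, 22 rose and 0 fell by limma over all genes, and 28 rose adjusted over the list alone. Of the 23 glycolysis genes, 16 rose (21 adjusted over the list alone), including SLC16A3 (2.50 ± 0.22) and the phosphoglycerate kinase PGK1 (1.94 ± 0.21). Collagens, laminins and basement membrane genes had 7 of 21 rise (11 adjusted over the list alone), among them COL7A1 (1.82). Secreted growth factors had 6 of 20 rise (9 up and 2 down adjusted over the list alone), including EFNA1 (1.39). Mesenchymal genes had 4 of 12 rise (5 adjusted over the list alone), TGFBI, VIM, CDH2 and THBS1. Matrix remodelling enzymes had 4 of 18 rise and CTSL fall (5 and 1 adjusted over the list alone). Inflammatory genes had CCL2, TNFAIP3 and BIRC3 rise of 15 (5 up and 2 down adjusted over the list alone), and integrins had SDC4 and ITGAV rise of 14 (4 adjusted over the list alone). Of 10 stem cell-associated genes POU5F1 and KLF4 rose (3 up and 1 down adjusted over the list alone).

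Mucins and goblet cell genes had 4 of 9 fall and 0 rise (6 down and 1 up adjusted over the list alone), including FCGBP (-2.56 ± 0.28) and MUC5AC (-1.95 ± 0.25). Of 18 stress response genes 4 fell (7 down and 2 up adjusted over the list alone), among them SDF2L1 (-1.42) and XBP1 (-1.05). NRF2 target genes had ALDH3A1 and AKR1C1 fall of 22 (7 down and 2 up adjusted over the list alone), and AKR1C1 has close paralogs that can share reads. Single genes passed in the remaining lists. CITED2 rose and HIF1A fell among 8 oxygen-sensing components, CLDN1 rose among 17 epithelial genes (4 up and 1 down adjusted over the list alone), LPCAT1 rose and FOXA1 fell among 6 lung lineage genes (2 and 2 adjusted over the list alone), OAS1 fell among 12 interferon-stimulated genes (1 and 1 adjusted over the list alone) and HIST1H4H rose among 7 histone genes. The counts for the oxygen-sensing and histone lists were the same adjusted over the list alone. The call of HIST1H4H is uncertain, since most histone transcripts of this kind lack a poly(A) tail. By limma, 0 genes passed of the 28 for oxidative phosphorylation, 20 for G2/M, 20 for cholesterol, 30 ribosomal proteins and 3 measured blood cell markers, over all genes and adjusted over the list alone. The 20 G1/S genes had 0 pass over all genes and 8 fall adjusted over the list alone.

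Over all 12663 genes, limma called 405 genes up and 208 down under hypoxia at an adjusted p below 0.05, and 3242 genes had an unadjusted p under 0.05. Without the filter on low values the calls dropped to 5 up and 0 down (3589 genes at an unadjusted p under 0.05), and after rescaling to a sum of 1000000 they were 303 up and 475 down, a share up of 38.9% in place of 66.1%. They were 755 and 531 without small RNA genes and genes listed at 0, 254 and 112 without trend, and 507 and 313 at a mean of at least 5 FPKM. The fit had 1 residual degree of freedom, which held noise together with any real difference between the cultures' responses.

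**Figure D2:**
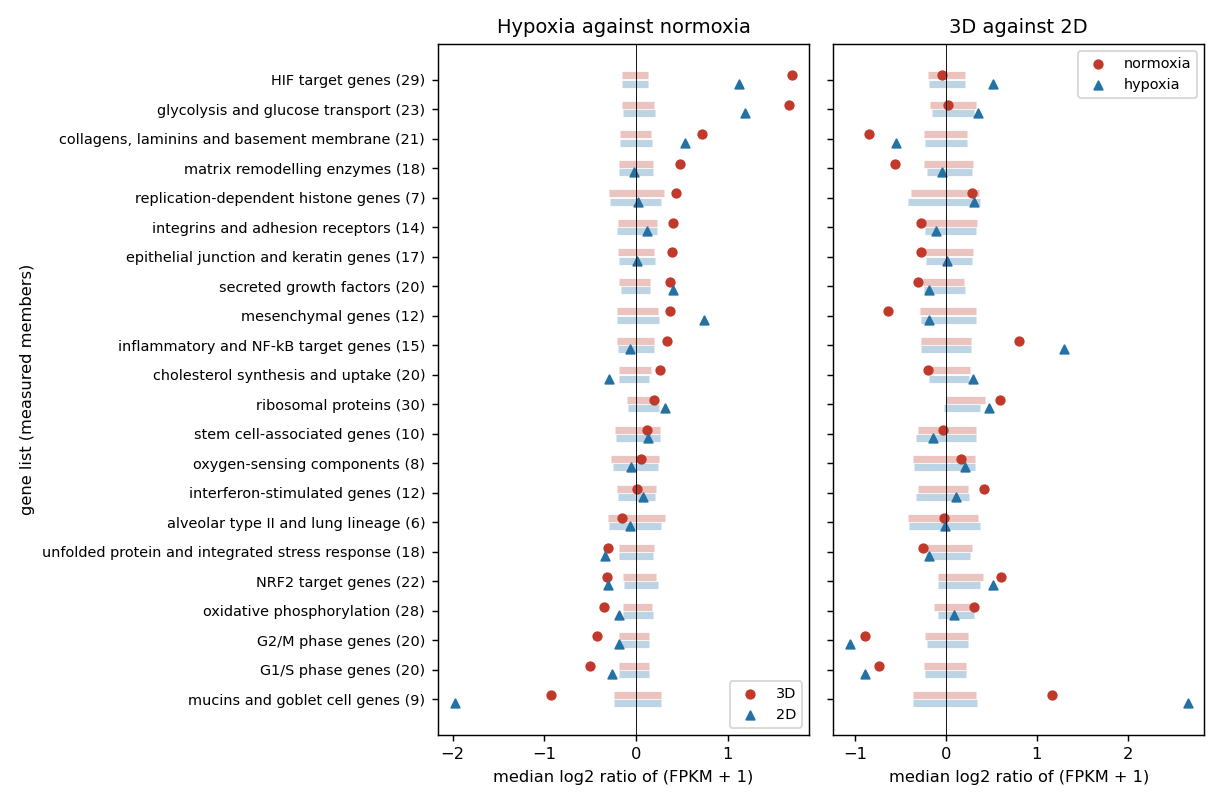
Points are the median log2 ratios (FPKM + 1) of fixed gene lists with at least 6 measured genes, 1 list left out, for hypoxia against normoxia on the left (3D circles, 2D triangles) and 3D against 2D on the right (normoxia circles, hypoxia triangles), and shaded bars are the central 95% of 10000 matched random lists. HIF target genes lie at 1.70 and 1.12 on the left and mucins at 1.16 and 2.66 on the right, and rescaling to a sum of 1000000 turned the sign of medians near 0, those for glycolysis (3D against 2D, normoxia), oxygen-sensing components (hypoxia in 3D, and 3D against 2D in normoxia), oxidative phosphorylation (3D against 2D, hypoxia), epithelial genes (hypoxia in 2D, and 3D against 2D in hypoxia), interferon-stimulated genes (all but 3D against 2D in normoxia) and histones (hypoxia in 2D), while scaling by median ratio turned those for lung lineage genes in both comparisons of 3D against 2D.

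The comparison of 3D with 2D in normoxia asked which genes differed with the culture on Matrigel without low oxygen. TCN1, a secreted vitamin B12 binding protein, was at 16.6 FPKM in 3D and 1.61 in 2D (log2 ratio 2.76), and ADH1C, CES1 (a carboxylesterase), FCGBP, S100P and AQP3 had ratios of 2.87, 2.59, 2.58, 2.50 and 2.49. RNVU1-20 was listed at 0 in 2D normoxia, and TMEM256-PLSCR3, a readthrough of neighbouring genes that share its fragments, was at 7.51 and 0.0135 FPKM and is uncertain. Among the lowest were the collagens COL5A1 (-2.70) and COL12A1 (-2.35), LOXL2 (-2.53), the cytokine IL11 (-2.50), the kinase anchor AKAP12 (-2.41), the drug efflux pump ABCB1 (-2.40) and PADI2, which converts arginine to citrulline (-2.36).

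Proliferation lists stood lower in 3D normoxia, with medians of -0.89 for G2/M genes, all 20 below 0 (MKI67 -1.50, CENPF -1.55), and -0.73 for G1/S genes (UHRF1 -1.18). Collagens, laminins and basement membrane genes had a median of -0.85, mesenchymal genes -0.63 (THBS1 -1.87, FN1 1.26), matrix remodelling enzymes -0.56 (PLAU -1.90), secreted growth factors -0.31 (CYR61 -1.78), epithelial genes -0.27 (KRT7 -1.22, KRT19 1.27), integrins -0.27 (ITGA3 -0.93) and stress response genes -0.25 (ASNS -0.92). Higher lists were mucins and goblet cell genes (1.16), inflammatory genes (0.81, with LCN2 at 1.63 and C3 at 1.51), NRF2 target genes (0.61, with GPX2 at 2.35 and HMOX1 at -1.35), ribosomal proteins (0.60, all 30 above 0) and interferon-stimulated genes (0.43, OAS1 1.05).

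Within their random ranges were oxidative phosphorylation (0.31), histones (0.28), cholesterol genes (-0.19), HIF targets (-0.05), stem cell-associated genes (-0.03, mean 0.13), glycolysis (0.02, mean -0.12, and -0.17 on rescaling to a sum of 1000000), oxygen-sensing components (0.17, and -0.03 on rescaling to a sum of 1000000) and lung lineage genes (-0.02, with the sign turned under scaling by median ratio). At least 2-fold differences numbered 251 higher and 315 lower in 3D, and 533 among genes with a known length, where counting noise gave a mean of 1.8. Rescaling to a sum of 1000000 gave 195 and 704, so that the share of higher genes went from 44.3% to 21.7%, with a median of all genes of -0.21.

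Under hypoxia the same comparison describes the condition with the structures against hypoxic cells on plastic. S100P was at 44.5 FPKM in 3D and 1.58 in 2D (log2 ratio 4.14), and TPPP3, a tubulin-binding protein, had a ratio of 3.92. AQP3 (3.69), MUC5B (3.64), the trefoil peptide TFF1 (3.63), the copper carrier CP (3.60), IGFBP1 (3.57) and the protease inhibitor CST1 (3.52) followed. TAGLN was at 8.75 FPKM in 3D and 227 in 2D (-4.55), COL5A1 at -4.15, COL4A1 at -3.19, COL1A1 at -3.13 and the proteoglycan SPOCK1 at -3.09. SNAR-E and P2RX6P were listed at 0 in 3D hypoxia.

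Mucins and goblet cell genes had a median of 2.66, all 9 above 0, and inflammatory genes 1.30, with PTGS2, the inducible prostaglandin synthase, at 3.06 and IL11 at -3.02. HIF target genes had a median of 0.52 (NDUFA4L2 2.75), NRF2 target genes 0.52, ribosomal proteins 0.47, glycolysis 0.35 (ALDOC 2.06) and cholesterol genes 0.30, all above their random ranges. G2/M and G1/S genes stood at -1.05 and -0.89, with all 20 of each below 0, and collagens, laminins and basement membrane genes at -0.55. Inside their random ranges were histones (0.31), oxygen-sensing components (0.21), mesenchymal genes (-0.19), secreted growth factors (-0.18), stress response genes (-0.18), stem cell-associated genes (-0.14, mean 0.20), integrins (-0.10) and matrix remodelling enzymes (-0.04). So were interferon-stimulated genes (0.11), oxidative phosphorylation (0.09) and epithelial genes (0.01), which changed sign on rescaling to a sum of 1000000 (-0.04, -0.10 and -0.19), and lung lineage genes (-0.01), which changed sign under scaling by median ratio (0.02).

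Of the 12663 genes 481 were at least 2-fold higher and 383 at least 2-fold lower in 3D, with 829 among those of known length, where counting noise gave a mean of 2.05. Rescaling to a sum of 1000000 gave 407 and 731, a share of 35.8% higher in place of 55.7%. Of the markers of other cells, 0 of 12 for endothelium and fibroblasts and 3 of 12 for blood cells reached a mean of 1 FPKM. Those 3 were CD68, CD14 and ITGAM, with a median log2 ratio of 0.29 in normoxia and 1.19 in hypoxia for 3D against 2D, and of -0.02 (mean 0.10) and -0.59 for hypoxia in 3D and 2D. The value of 1.19 lay above and that of -0.59 below the random range of this list of 3 genes.

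Averaged over both oxygen levels, TCN1 (2.85 ± 0.14), the tetraspanins TSPAN7 (2.35 ± 0.12) and TSPAN8 (2.31 ± 0.13), the trypsinogen PRSS3 (2.42 ± 0.12), the calcium-binding TESC (2.33 ± 0.13) and ZDHHC8P1 (2.22 ± 0.12) rose in 3D, each with a limma adjusted p of 0.00238. PRSS3 has close paralogs and ZDHHC8P1 is a pseudogene, so both are uncertain. NTS, which encodes neurotensin, fell by 2.34 ± 0.12 on the log2 scale with the same adjusted p, and PADI2 (-2.51), the Wnt receptor FZD8 (-1.95), OLFML3 (-1.82) and IL11 (-2.76) fell as well.

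Of 20 G2/M genes 18 fell by limma (19 adjusted over the list alone), including MKI67 (-1.58 ± 0.12), and of 20 G1/S genes 14 fell (17 adjusted over the list alone). Collagens, laminins and basement membrane genes had 13 of 21 fall and LAMB3 rise (14 and 1 adjusted over the list alone), and matrix remodelling enzymes 5 fall and 1 rise of 18, the same adjusted over the list alone. Stress response genes had 8 fall and 2 rise of 18 (8 and 3 adjusted over the list alone), growth factors 5 fall and 2 rise of 20 (6 and 3 adjusted over the list alone), mesenchymal genes 4 fall and 3 rise of 12 (5 and 3 adjusted over the list alone), and integrins ITGB1 and ITGA3 fall of 14 (3 down and 1 up adjusted over the list alone). Mucins had 7 of 9 rise, the same adjusted over the list alone, with MUC5AC at 2.93 ± 0.25. NRF2 target genes had 11 rise and HMOX1 fall of 22 (13 and 2 adjusted over the list alone), inflammatory genes 10 rise and IL11 fall of 15 (12 and 2 adjusted over the list alone), and ribosomal proteins 11 of 30 rise (25 adjusted over the list alone), though many of these have processed pseudogenes that can share reads.

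HIF target genes had 7 rise and 2 fall of 29 (10 and 3 adjusted over the list alone), glycolysis genes 2 and 2 of 23 (1 and 2 adjusted over the list alone), interferon-stimulated genes 4 and 2 of 12, the same adjusted over the list alone, and epithelial genes 4 and 3 of 17 (4 and 5 adjusted over the list alone). Oxygen-sensing components had CITED2 and ARNT2 rise, the same adjusted over the list alone. Oxidative phosphorylation had NDUFV2, SDHD and SDHC rise (1 adjusted over the list alone). Lung lineage genes had FOXA1 rise and LPCAT1 and ABCA3 fall (3 and 3 adjusted over the list alone). Stem cell-associated genes had 3 rise and SOX2 fall of 10, the same adjusted over the list alone. Cholesterol genes had 1 rise and 1 fall of 20 (0 adjusted over the list alone). Histones had HIST1H2BC rise (0 adjusted over the list alone), which is uncertain for the same reason as HIST1H4H above. Blood cell markers had CD68 rise, the same adjusted over the list alone.

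In all, limma called 1313 genes up and 1472 down in 3D, and 5097 had an unadjusted p under 0.05. Without the filter on low values 1 and 2 remained, and rescaling to a sum of 1000000 gave 767 and 3132, a share up of 19.7% in place of 47.1%. Scaling by median ratio turned the majority, with 1367 up and 1229 down.

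**Figure D3:**
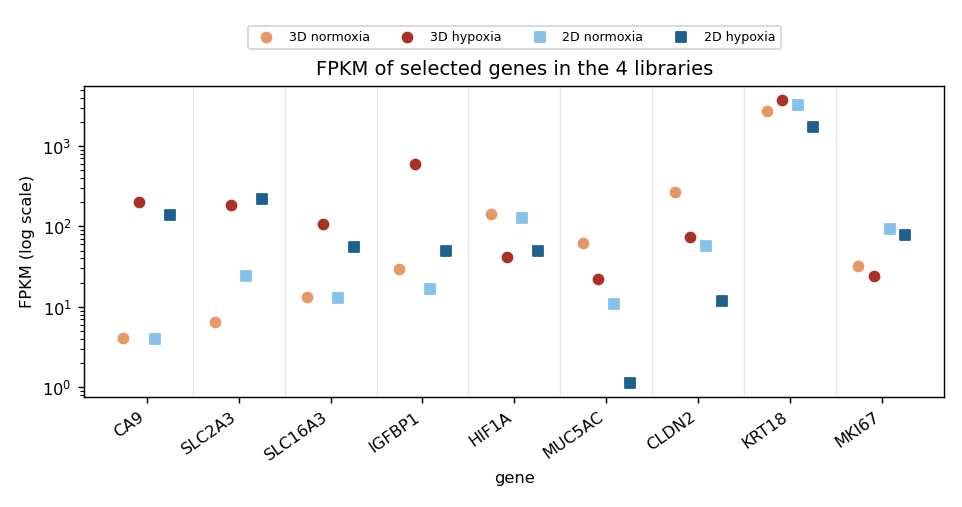
Points are the FPKM of 9 genes on a log axis in the 4 libraries, 3D as circles and 2D as squares, with normoxia in the paler and hypoxia in the darker shade. CA9 is near 4 FPKM in both normoxia libraries and at 199.7 and 138.5 FPKM in hypoxia, whereas IGFBP1 reaches 604.3 FPKM in 3D hypoxia and 50.1 in 2D hypoxia.

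The last question was how far the response to hypoxia differed between the cultures. NDUFA4L2 had the largest difference of log2 ratios (3D minus 2D) among the genes eligible to be named, 2.94, from 0.314 to 12.1 FPKM in 3D and 0.50 to 0.957 in 2D. IGFBP1 followed at 2.76, INHA, the inhibin alpha chain, at 2.48, TFF1 at 2.46, SMOC1, a matrix protein, at 2.41 and PTGS2 at 2.26. TAGLN had a difference of -2.38, and the others at that end were the uncertain H3F3A (-2.58) and TMEM256-PLSCR3 (-2.99) and the genes listed at 0 in some libraries, SNAR-E, P2RX6P and RNVU1-20. Median differences above the random ranges were found for mucins (1.46), inflammatory genes (0.91), cholesterol genes (0.58, all 20 above 0), HIF targets (0.47, 28 of 29 above 0), matrix remodelling enzymes (0.46), blood cell markers (0.57, 3 genes), glycolysis (0.45), epithelial genes (0.40), integrins (0.35), stress response genes (0.19) and growth factors (0.18, mean -0.03). Medians below them were found for G1/S genes (-0.29), oxidative phosphorylation (-0.21) and G2/M genes (-0.18). A difference above 0 need not be a larger rise in 3D. Mucins had median hypoxia log2 ratios of -0.92 in 3D and -1.98 in 2D, and stress response genes of -0.30 and -0.34. Both lists were thus lower under hypoxia in both cultures. For matrix remodelling enzymes, the median for 3D against 2D was -0.56 in normoxia and -0.04 in hypoxia. Whether the level in normoxia accounts for their difference was not tested.

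A difference of at least 2-fold separated the responses of 237 genes toward 3D and 109 toward 2D, of which 34 and 38 were small RNA genes. The counts were 203 and 60 without small RNA genes and genes listed at 0, 176 and 51 at a mean of at least 5 FPKM, and 428 and 179 with a pseudocount of 0.1 FPKM. Across the 12663 genes, the hypoxia log2 ratios in 3D and 2D, which share no library, had Pearson r 0.44 and Spearman correlation 0.58, and 70.8% of genes had the same sign (genes are not independent replicates). Of the genes at least 2-fold apart, 137 were higher and 66 lower in both cultures, where independent lists would share 7.41 and 2.24, and 7 and 7 went opposite ways. The ratios of 3D against 2D in normoxia and in hypoxia had Pearson r 0.58 and Spearman correlation 0.73. Of the variation among the 4 libraries, culture held 50.9% of the sum of squares, oxygen 35.4% and the remainder 13.7%, or 8.03% without small RNA genes and genes listed at 0. The difference of responses leaves no residual degree of freedom, so it was not tested for any gene or list.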

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

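Of the tests in this part, those on library scaling, on the level in the 2D normoxia library and on small RNA genes were chosen only after the result was seen. TPPP3 was noticed because its hypoxia log2 ratio was 1.02 in 3D and -1.14 in 2D, opposite ways in the 1 library pair of each culture. The difference was not tested.

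Cholesterol synthesis and uptake genes drew attention because their median hypoxia log2 ratio was 0.26 in 3D and -0.29 in 2D, a difference that was not tested against replicates. The median difference of responses over all genes was -0.0142, against 0.58 for the list. As deposited, all-gene medians were near 0 in every comparison, which normalisation may have set, so they cannot show a scaling error. A shift from library scaling would move all genes nearly alike, so it would not part the list from matched random lists (-0.13 to 0.16). After rescaling to a sum of 1000000 the list stayed at 0.14 in 3D and -0.43 in 2D. With all libraries thinned to 11300000 fragments the list's median difference was 0.58 (SD 0.026 over 20 draws). Thinning mainly lowers the deeper 2D libraries and cannot undo noise or bias already in the 3D libraries. It shows only that the difference stays when the 2D libraries are made as shallow as those of 3D. A different sterol supply or demand of the cells in 3D under low oxygen remains a hypothesis that these libraries may point to but cannot test. A chance difference between single cultures also stays open, since each condition has 1 library.

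HIF target genes had larger hypoxia ratios in 3D, with a median difference of 0.47 and 28 of 29 members above 0. The median over all genes, -0.0142, again cannot show a scaling error. A shared shift would not part the list from matched random lists, though, and those ran from -0.12 to 0.13. Thinning to equal depth left a median difference of 0.49 (SD 0.086), with the same limit as for the cholesterol list. A higher starting level in the 2D normoxia library, as crowded cells might have, would lower the ratio in 2D, but the list's median for 3D against 2D in normoxia was -0.0462 with members both ways (12 above and 17 below 0, SD 0.833). In hypoxia that median was 0.52 with 23 of 29 above 0 (SD of members 0.998). By median the gap lay mainly in the hypoxia libraries, but the list means were -0.20 in normoxia and 0.44 in hypoxia. Members parted, with ADM at -1.56 in normoxia and -0.18 in hypoxia, and HILPDA at 0.28 and 1.57. The members spread wider than either median, and a culture difference at both oxygen levels would hide a raised baseline. The explanations therefore cannot be told apart for this list. Lower oxygen around cells in 3D than in 2D at the same setting may be a reason, and it was not tested.

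Small RNA genes were frequent among large differences, since 38 of 100 were at least 2-fold apart for hypoxia in 3D (38.0%), against 4.49% of other genes of like level, and 72 of 100 were listed at 0 in at least 1 library. If a few fragments on very short genes were the whole reason, the direction would be random between cultures. Of the 50 with a ratio other than exactly 0 in both cultures, 32 moved the same way, 64.0% (95% Wilson interval 50.1% to 75.9%), just above an even split. That interval treats the genes as independent and counts ratios against values listed at 0. The genes were picked by symbol, which takes in MIR210 and its host transcript MIR210HG, whose fragments overlap. It therefore cannot decide whether that explanation is the whole cause. A mix of counting noise, fragments of overlapping transcripts and some real change may fit these values, and no biological explanation was tested.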

How the results depend on the processing

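The setting without small RNA genes and genes listed at 0 was chosen only after the results were seen; the rest were planned. No list median outside its random range changed sign. Nor did any gene at least 2-fold apart among the highest and lowest named genes of each comparison. A pseudocount cannot turn the sign of a pairwise ratio, so the result for genes says little. The majority of higher or lower genes did turn with sums of 1000000, for hypoxia in 2D (40.9% higher), 3D against 2D in hypoxia (35.8%) and the average hypoxia effect (38.9%), as it did for the average effect of 3D with median ratio scaling (52.7%) and for hypoxia in 2D with a pseudocount of 0.1 FPKM (49.7%). For the counts below that moved by over 1.5 times the cause was not tested. With a pseudocount of 0.1 FPKM, genes at least 2-fold lower numbered 227 (hypoxia in 3D), 351 (hypoxia in 2D), 534 (3D against 2D, normoxia) and 599 (hypoxia), genes higher in 3D normoxia 390, differing responses 428 and 179, and r between the hypoxia ratios was 0.34. With a mean of at least 5 FPKM, 81 genes were lower for hypoxia in 3D, 250 for 3D against 2D in hypoxia and 51 for the difference of responses, and limma called 313 down under hypoxia. With sums of 1000000, 236, 341, 704 and 731 genes were lower in the 4 pairs, and limma called 475 down under hypoxia and 767 up and 3132 down in 3D. Without the filter limma called 5 up and 0 down under hypoxia (3589 at an unadjusted p under 0.05) and 1 and 2 in 3D, and without trend 254 and 112 under hypoxia. Without small RNA genes and genes at 0, 60 genes differed toward 2D, r was 0.65 and limma called 755 and 531 under hypoxia. Of the 613 hypoxia calls, 470 were shared under median ratio scaling, 510 with sums of 1000000, 557 with robust limma, 356 without trend and 5 without the filter. Of 204 list medians and named genes, 173 moved by less than 1.5-fold with a pseudocount of 0.1, 186 with sums of 1000000 and 204 with median ratio scaling, though medians near 0 could change sign within that. No library could be left out, since 3 libraries leave the fit no residual degree of freedom. No paired analysis was possible because each group has 1 library and the labels give no replicate numbers. The 3D libraries, at 11800000 and 11300000 fragments, limit low genes most.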

Other observations

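The families in this part were chosen only after their values were seen, 6 of 26 symbol patterns looked at, and the plasma protein set was put together by hand from genes already viewed, so their medians are descriptions. All but the aldehyde dehydrogenases have a membership that differs from the pattern first looked at, which mattered most for 3 families. Insulin-like growth factor binding proteins had a median hypoxia log2 ratio of 1.90 in 3D, all 7 above 0, and 0.40 in 2D (1.77 and 0.16 for the 8 genes of the pattern). IGFBP3, the most abundant of them under hypoxia, was at 262.9 and 1382 FPKM in 3D and 132.5 and 707.4 in 2D and rose by 2.40 ± 0.14 (limma adjusted p = 0.00456), and IGFBP7 rose as well, whereas IGFBP6 was at 1.90 in 3D and -0.22 in 2D. Plasma proteins, normally made by the liver, had a median of -0.05 (mean 0.02) for hypoxia in 3D and -0.95 in 2D, with 17 of 18 differences above 0, and 1.29 for 3D against 2D in hypoxia. The pattern first looked at, 34 genes that include most of these, had much smaller values, -0.23 for hypoxia in 2D, 0.28 for the median difference and 0.40 for 3D against 2D in hypoxia. Among them VTN, which encodes vitronectin, was at 0.11 in 3D and -1.43 in 2D, and the iron carrier TF at 1.51 and -0.50. Limma called 4 of the 18 down under hypoxia, among them APOH (-1.85 ± 0.19), and 9 up and 2 down in 3D. The difference between cultures was not tested.

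Aldehyde dehydrogenases had medians of -0.40 and -0.20 for hypoxia in 3D and 2D and of 0.39 and 0.32 for 3D against 2D, with 3 of 16 falling under hypoxia and 7 rising and 2 falling in 3D by limma. Cytosolic aminoacyl-tRNA synthetases stood at -0.26 for hypoxia in both cultures, with DARS alone of the 20 passing limma (0.75 ± 0.12, up), and 9 of 20 fell in 3D. A set of 10 alpha and beta tubulins, without TUBB and TUBAL3, stood at 0.44 and 0.27 for hypoxia, against 0.07 and 0.11 for the 22 genes of the wider pattern, with TUBB6 rising (1.02 ± 0.14) and TUBA1A at 1.97 in 3D and 0.57 in 2D. Proteasome subunits stood at -0.22 for hypoxia in 3D and -0.10 in 2D (random range -0.13 to 0.14), with 0 of 37 passing limma for hypoxia. Over all 12663 genes 613 passed, and 3242 had an unadjusted p under 0.05. The median of the proteasome subunits for 3D against 2D was 0.10 in normoxia (-0.10 with sums of 1000000) and -0.02 in hypoxia (0.01 under median ratio scaling).

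Some single genes, also picked after their values were seen, stand out. The keratins KRT8 and KRT18, which pair in simple epithelia, moved together, at 0.39 and 0.45 for hypoxia in 3D and at -0.72 and -0.93 in 2D. MIR210HG, the host transcript of a hypoxia-associated microRNA, rose by 2.45 ± 0.30 (limma adjusted p = 0.0202), and MIR210 was at 385.0 FPKM in 3D hypoxia and 112.4 in 2D hypoxia and listed at 0 in both normoxia libraries. Its fragments cannot be told from those of the host transcript that overlaps it. The metallothionein MT1X rose by 1.83 ± 0.25 and HLA-DMA fell by 1.35 ± 0.13 beside HLA-DMB, while FTL, the ferritin light chain, rose by 1.10 ± 0.23 in 3D. MT1X and FTL have near-identical relatives that can share reads.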
